A study of Mus musculus with 9 samples.

How the data were processed

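Each of 9 samples of total RNA from C2C12 cells was hybridised to a 1-colour array of 44397 spots, with 3 samples per group per the labels. Of the deposited scanner files, the processed signal, mean signal and background columns hold intensity values on a linear scale, per the file headers, and the columns of other kinds are 0 or 1 marks for control, non-uniform, saturated and well-above-background spots, per the file headers. The scanner software was Agilent Feature Extraction 11.5.1.1, per the submitters' processing notes, which also name limma without a version. The deposited series table holds log2 values of 30094 probes. Its column medians ran from 9.65 to 9.73, and its columns correlated at 0.9997 to 0.9999 with values made here by normexp correction and quantile normalization, so its genes were not centred. It served as an alternative only.

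The main setting took log2 of the processed signal minus each array's 75th percentile of it. Control spots were left out, leaving 43020 spots of 39429 probes, as were spots marked as non-uniform outliers, and spots of 1 probe were averaged. A probe was kept if it was well above background on all 3 arrays of at least 1 group, which held for 28339 probes (71.9%). A gene was represented by its kept probe with the highest mean, giving 21926 genes, of which 20150 had a value on all arrays. Names came from a reference gene table of assembly GRCm38.p6, used for names only, by accession for 21033 kept probes and by symbol for 2168, while 5138 kept the name in the files. Probe coordinates are those of the mm9 build in the files. Probes of a gene could disagree. For C3 the log2 changes were 6.18 and 2.64 at 1 nM, for Cpt1a 1.14 and 0.28, for Insr 1.11 and 0.17, for Hmox1 0.72 and 0.24, for Nfatc2 -1.44 and -0.42, for Igf1 1.16 and 0.05, for Tbc1d4 0.82 and -0.12, for Mbp -1.15 and 0.35, and for Hsd17b7 -0.34 and -1.12.

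Each dose was compared with vehicle, and 10 nM with 1 nM, by limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 fit of all groups without a block, with Benjamini-Hochberg adjustment and a threshold of 0.05. The tests, the 25 gene lists, the rule for named genes and most alternatives were chosen before the data were examined. That the replicates are separate cultures rests on the series' design text. The rule named the 12 highest and 12 lowest called genes of each dose against vehicle, and the 5 highest and 5 lowest between the doses, among genes whose groups did not overlap. It added up to 4 called members per list with the smallest p, or 2 members where none was called, and always Cyp24a1 and Vdr. Probe numbers, accessions and clone names were not named, and some genes that the rule took are not reported here. Lists of at least 5 measured members were tested with camera, at a preset correlation of 0.01 and with an estimated one, on genes with a value on all arrays. Camera called 17, 17 and 16 of 25 lists at 1 nM, at 10 nM and between the doses, and 1, 3 and 3 with the estimated correlation. Limma's fry, which tests whether a list's genes move on balance in 1 direction and does not set them against other genes, called 24, 24 and 15.

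In a check of whether replicate numbers pair the samples, from the data and not the labels, the deviations from group means of the 1 nM and 10 nM arrays of the same number correlated at 0.483, 0.33 and 0.142 across genes. Those numbers were therefore taken as pairs for the comparison of the doses, and the vehicle numbers were not. The main setting stayed without a block, and the blocked value is given where it ended a call or moved a count by over 1.5 times. Slide and scan date divided the arrays the same way, and the slide was tested as a block and within each slide that held more than 1 group. The closest pair of arrays differed by an SD of 0.262 on the log2 scale, with 0 identical values, and each array was counted as 1 sample.

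The procedure was tested on 20150 simulated genes with known changes. Of genes changed by 0.5, 1 and 2 on the log2 scale, 10.6%, 65.7% and 83.6% were recovered at 1 nM, 21.2%, 55.2% and 85.1% at 10 nM, and 21.2%, 64.2% and 94.0% between the doses. Unchanged genes were called 6, 12 and 5 times. The list test found 1 of 1 changed list and 0 of 24 unchanged ones, which need not hold for correlated lists. For the overlap of the doses, 100 simulations drew unchanged groups and a shared vehicle group of equal spread. Alternatives covered background correction, scaling, the submitters' table, the probe filter, probe choice, spread model and array weights. Others were groups fitted, replicate and slide blocks, each array left out and stricter thresholds. Gene structure around the probes was not analysed here.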

Results

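Gene expression was measured in C2C12 cells, a mouse myoblast line that fuses into multinucleated myotubes when growth serum is withdrawn, after 72 h with vehicle or with 1 nM or 10 nM calcitriol, the hormonal form of vitamin D and the ligand of the vitamin D receptor. The series speaks of myotubes, and the stage at which treatment began was not given in the sources used here. Total RNA was labelled with the green dye Cy3 and each of 9 samples was hybridised to its own 1-colour array, with 3 biological replicates per group per the series' design text. The 75th percentile of the processed signal ran from 2826 to 3389 intensity units and no spot was saturated. On 8 arrays 67.1% to 79.2% of spots were well above background, and on the array of vehicle replicate 3 the share was 96.4%. After filtering, 21926 genes were tested on 9 arrays, and their number limits the precision.

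The array of vehicle replicate 3 stood apart from the other 8. Its scanner file marked 6124 spots (13.8%) as non-uniform, against 8 to 56 spots on the other arrays, so 1699 of the genes tested had no value there, against 1 to 37. Its median signal was 660 against 216 to 315, its 25th percentile 243 against 15.8 to 40, and its negative control spots had a raw median of 44 against 27 to 31. The excess over the other vehicle arrays lay in dim probes, with a median log2 excess of 3.83 in the lowest 10% by level and -0.09 in the highest 10%. Correlations between vehicle arrays ran from 0.9686 to 0.9948, against 0.9937 to 0.9972 within 1 nM and 0.9917 to 0.9938 within 10 nM. Values without this array are given where they move the call of a list or of a gene named for that comparison.

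Cyp24a1, the enzyme that breaks down the hormone and a direct target of its receptor, rose at both doses. On the log2 scale relative to the array's 75th percentile it averaged -5.19 ± 0.47 (SD, n = 3) in vehicle, -3.90 ± 0.15 at 1 nM and 0.94 ± 0.02 at 10 nM. That is 2.45-fold higher at 1 nM (log2 1.29, SE 0.22, adjusted p = 0.00385) and 70.2-fold higher at 10 nM (log2 6.13, adjusted p = 7.32e-07), and 28.6-fold higher at 10 nM than at 1 nM (adjusted p = 0.000151). The 1 nM call was lost with quantile normalization (log2 2.42, adjusted p = 0.108) and within slide 1 (log2 1.16, adjusted p = 0.151), in a range of 4.50e-05 to 0.151 over its alternatives. Vdr, the receptor itself, averaged 2.03 ± 0.07, 2.12 ± 0.06 and 3.64 ± 0.05 (SD, n = 3). It rose 3.06-fold at 10 nM (log2 1.61, SE 0.07, adjusted p = 1.96e-06), while its 1 nM difference of 0.10 on the log2 scale (adjusted p = 0.356) did not pass the test. The Cyp24a1 probe lies on chromosome 2, 170308865 to 170308924, minus strand, and the Vdr probe on chromosome 15, 97685136 to 97685195, minus strand, in the mm9 build per the file headers. Whether a probe lies in a coding exon or an untranslated region was not given in the sources used here.

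**Figure D1:**
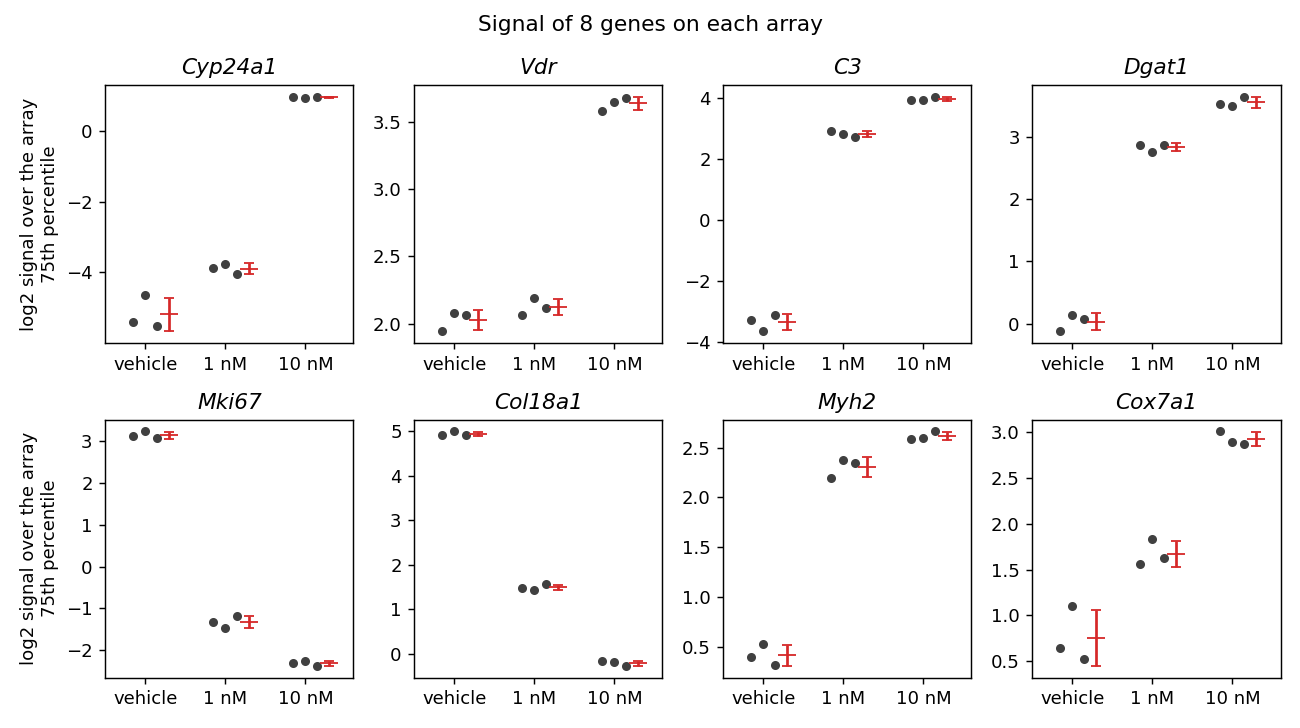
Expression of 8 named genes on each of 9 arrays, with the y axis the log2 signal relative to the array's 75th percentile, points for the arrays of each group, and bars for the mean ± SD (n = 3). Cyp24a1 averaged -5.19 in vehicle, -3.90 at 1 nM and 0.94 at 10 nM, and Mki67 and Col18a1 were lower at both doses than in vehicle.

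The comparison of 1 nM with vehicle (n = 3 per group) addresses what the lower dose does to myotube expression. The highest genes included C3 and Cfb. C3, the central complement protein, rose 72.7-fold (log2 6.18, SE 0.14, with another probe of the gene at 2.64), Cfb, a protease of the alternative complement pathway, 66.8-fold, Rarres2, which encodes the chemoattractant adipokine chemerin, 108-fold, and Orm2, an acute-phase glycoprotein, 54.7-fold. S100g, an intestinal calcium-binding protein known as a vitamin D target, rose at least 51.1-fold, Grpr, a neuropeptide receptor, at least 44.8-fold and Sprr2h at least 28.8-fold. Lowest were Car9 (130.4-fold down, SE 0.24 on the log2 scale) and Car12 (44.3-fold down), carbonic anhydrases known to be induced by low oxygen, and the matrix protein genes Aspn (at least 29.3-fold down) and Cilp (26.8-fold down). Genes that act in mitosis or DNA repair were also among the lowest, namely Esco2 (at least 17.0-fold down), Kif15 (at least 17.4-fold down), Neil3 (at least 34.8-fold down), Cenpf (at least 10.2-fold down), Ska1 (32.4-fold down) and Depdc1a (24.7-fold down). Car12 and Depdc1a were above background on 2 of 3 arrays at 1 nM. Adjusted p was at most 0.000319 for each of these genes. A fold written as at least N sets the bright group's mean over all replicates against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the dim probe's own, as means of normalized log2 values.

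Mmp13 and Mmp3, matrix-degrading proteases, Wfdc17, a secreted protease inhibitor, and Fabp4, a fatty acid carrier of adipocytes, were well above background on 1 of 3 vehicle arrays. They rose by 8.27, 6.75, 7.19 and 6.94 on the log2 scale (adjusted p = 0.00139, 0.00213, 0.00157 and 0.00318). Without vehicle replicate 3 these values were 9.78, 8.08, 8.53 and 8.45, which as bounds are at least 183-fold, 68.9-fold, 89.3-fold and 112-fold. Without vehicle replicate 1 they were 7.30, 5.88, 6.32 and 6.23, and Fabp4 was 6.15 without vehicle replicate 2. Srcin1, an adaptor of Src signalling above background on 1 of 3 vehicle arrays, rose by 5.37 (4.58 without vehicle replicate 2), and Grpr by 7.20 as fitted (6.30 and 8.10 without vehicle replicates 1 and 2). Efcab11 fell by 4.71 on the log2 scale (at least 9.18-fold, and -3.72 or at least 4.64-fold without vehicle replicate 3), and Defb48, a defensin above background on 1 of 3 treated arrays, fell 25.6-fold.

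With limma and Benjamini-Hochberg adjustment 5186 of 21926 genes (23.7%) passed an adjusted p of 0.05, 2587 higher and 2599 lower, with a median SE of 0.13. A change of at least 2-fold was found in 455 higher and 998 lower genes. The groups did not overlap in 9308 genes (42.5%, against 10% by chance). With the slide as a block 4823 genes were called, 1594 within slide 1 and 10421 within slide 2, where vehicle replicate 3 is the only vehicle array. Slide 1 held vehicle replicates 1 and 2 and 1 array of each dose, and slide 2 held 1 vehicle array, 2 at 1 nM and 1 at 10 nM, so each within-slide spread came from 1 pair of arrays and lone arrays are assumed to vary alike. In all, 85 of 118 named genes kept their call within slide 1, and without vehicle replicate 3 the count was 5568. The 75th percentile and the median put the array of vehicle replicate 3 on different levels. Scaled by the 75th percentile, its median was -2.14 on the log2 scale, against -3.88 to -3.50 on the other arrays. The median change of all genes was -0.09 at 1 nM and -0.11 at 10 nM, and it became 0.38 and 0.40 when each array was scaled to its median. That scaling called 1512 genes at 1 nM with 62.2% higher, against 49.9% in the main setting. For the gene lists that follow, adjusted p is that of limma's camera test, which sets a list against the other genes with a preset correlation unless an estimated one is named.

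Genes of proliferation fell almost without exception at 1 nM. Of 40 measured cell cycle and DNA replication genes 0 rose and 39 fell (0 and 39 adjusted over the list alone), with adjusted p = 3.50e-35, or 0.0180 with an estimated correlation. Where 2 adjusted p follow for a list, the second has an estimated correlation. Mki67, a marker of cycling cells, fell 22.3-fold (SE 0.09 on the log2 scale), the survivin gene Birc5 19.3-fold, cyclin A2 (Ccna2) 16.7-fold and the mitotic kinesin Kif20a 11.6-fold. The list's median was -3.73, or -3.59 with members below background at their bound, and -3.71, -3.70 and -3.73 with the slide as a block and within slides 1 and 2. Myoblast and satellite cell markers moved both ways (4 rose and 7 fell of 16 measured, 4 and 7 adjusted over the list alone, adjusted p = 0.316), with a median of -0.20 that became 0.17 under array median scaling. Cd34, a marker of quiescent satellite cells, fell 10.3-fold and Msc, a repressor of differentiation, 7.50-fold, while Id3, an inhibitor of myogenic factors, rose 4.43-fold and the chemokine receptor gene Cxcr4 2.61-fold.

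Contractile and calcium-handling genes were higher at 1 nM. Of the sarcomere list 30 rose and 1 fell of 46 measured, 36 and 2 adjusted over the list alone, with adjusted p = 4.20e-13 and 0.104. The fast myosin gene Myh2 rose 3.70-fold, the slow myosin gene Myh7 2.49-fold, the slow light chain Myl2 3.01-fold and the M-band protein Myom3 1.59-fold. In the calcium handling list 16 rose and 0 fell of 27 measured, 19 and 0 adjusted over the list alone, with adjusted p = 1.81e-09 and 0.0781. Examples were Cacna2d1, a calcium channel subunit (2.61-fold), and Atp2a2, the slow-muscle calcium pump (1.82-fold). The sarcomere median of 0.49 was 0.49, 0.36 and 0.59 with the slide as a block and within slides 1 and 2, and the calcium median of 0.48 was 0.47, 0.44 and 0.56. Among regulators of myogenic differentiation and fusion 10 rose and 3 fell of 26 measured, 14 and 5 adjusted over the list alone, with adjusted p = 0.00796 and 0.231. The growth factor binding protein gene Igfbp5 rose 3.06-fold and the growth factor gene Igf1 2.23-fold, whereas the cell cycle inhibitor gene Cdkn1c fell 5.30-fold and Nfatc2, a factor of myotube growth, 2.72-fold. The myogenic call was lost under 6 of 18 alternatives (adjusted p = 0.000157 to 0.231), among them without vehicle replicate 3 (0.0926) and within slide 1 (0.130).

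Mitochondrial genes were modestly higher. In the oxidative phosphorylation list 20 rose and 0 fell of 69 measured, 22 and 0 adjusted over the list alone, with adjusted p = 1.10e-09 and 0.129. The muscle cytochrome oxidase subunit genes Cox7a1 and Cox8b rose 1.89-fold and 1.53-fold. The median of 0.20 was 0.20, 0.14 and 0.28 with the slide as a block and within slides 1 and 2. In the fatty acid oxidation list 13 rose and 0 fell of 35 measured, 16 and 0 adjusted over the list alone, with adjusted p = 8.41e-06 and 0.0781. The fatty acid carrier gene Fabp3 rose 2.31-fold and Cpt1a, which takes fatty acids into mitochondria, 2.20-fold (with another probe at log2 0.28). Glycolysis genes were lower on balance. Of these 6 rose and 14 fell of 25 measured, 6 and 15 adjusted over the list alone, with adjusted p = 0.00686 and 0.266. The median of -0.47 became 0.02 under array median scaling, or -0.39 also without vehicle replicate 3. The lactate exporter Slc16a3 fell 6.52-fold, Aldoc 4.71-fold and Pdk1, which restrains pyruvate oxidation, 3.99-fold, while Ldhb rose 3.30-fold. In the insulin signalling list 10 rose and 3 fell of 30 measured, 13 and 3 adjusted over the list alone, with adjusted p = 0.000688 and 0.182. Insr, the insulin receptor gene, rose 2.15-fold while the glucose transporter gene Slc2a1 fell 2.11-fold. The glycolysis call was lost within slide 2, and the insulin call under 3 of 18 alternatives (adjusted p = 3.22e-05 to 0.182). Those 3 were the normexp and quantile settings and the estimated correlation.

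Cholesterol synthesis genes fell together at 1 nM. Of the list 1 rose and 21 fell of 24 measured, 1 and 21 adjusted over the list alone, with adjusted p = 2.06e-11 and 0.0781. Stard4, a sterol carrier, fell 3.98-fold, Cyp51 2.41-fold and Fdps 2.20-fold. The median of -1.06 was -1.11, -1.10 and -1.04 with the slide as a block and within slides 1 and 2. Lipogenesis and triglyceride storage genes went both ways (6 rose and 12 fell of 28 measured, 7 and 12 adjusted over the list alone, adjusted p = 0.450). Dgat1, which completes triglyceride synthesis, rose 6.96-fold and the lipid droplet coat gene Plin2 2.38-fold, while Elovl6, a fatty acid elongase, fell 4.71-fold and G0s2, an inhibitor of lipolysis, 3.21-fold. The lipogenesis median was -0.05 and 0.44 under array median scaling, the mean relative to other genes was 0.06, and camera ranked the list down. Of the adipocyte markers 5 rose and 0 fell of 14 measured, 5 and 0 adjusted over the list alone, among them the transcription factor gene Cebpa (3.60-fold) and Cebpb (1.82-fold), with adjusted p = 0.0860. Their median of -0.20 and mean of 0.67 differed in sign, and the median became 0.29 under array median scaling. Without vehicle replicate 3, where dim probes read higher, 7 adipocyte markers rose, 0 fell and the list was called (0.00156, 0.000444 to 0.970 over its alternatives). The adipocyte member Plin4 rose 1.53-fold (adjusted p = 0.0185), a call lost without vehicle replicate 1, 1 nM replicate 2 or 1 nM replicate 3 (0.0592 to 0.0704).

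Extracellular matrix genes were lower at 1 nM. In the list 9 rose and 27 fell of 46 measured, 9 and 29 adjusted over the list alone, with adjusted p = 1.37e-05 and 0.0685. Col18a1, the source of endostatin, fell 10.9-fold (SE 0.07 on the log2 scale), Col5a3 9.68-fold, Col6a1 6.80-fold and Col5a1 5.24-fold. The median of -0.56 was -0.56, -0.63 and -0.50 with the slide as a block and within slides 1 and 2. Fibroblast and smooth muscle markers fell in larger part (2 rose and 10 fell of 14 measured, 2 and 10 adjusted over the list alone, adjusted p = 0.000222 and 0.0685). Cnn1, a smooth muscle calponin, fell 6.91-fold, Tagln 2.57-fold and S100a4 2.12-fold. The median of -0.72 was -0.69, -0.74 and -0.65 in the slide settings. Within slide 2 the calls of the matrix and fibroblast lists were lost. Of the Notch, TGF-beta and BMP response list 4 rose and 9 fell of 28 measured, 4 and 10 adjusted over the list alone, with adjusted p = 0.0839 and a median of -0.16 (0.33 under array median scaling). The activin subunit gene Inhba fell 4.29-fold and the Notch ligand gene Jag1 2.64-fold. Without vehicle replicate 3 this list was called (0.0311, 0.00504 to 0.970 over its alternatives). Of osteoblast and chondrocyte markers, which include probes near background, 3 rose and 4 fell of 16 measured, 3 and 5 adjusted over the list alone, with adjusted p = 0.337 and a median of -0.27 (0.02 under array median scaling). Dmp1, a bone matrix protein, fell 19.6-fold and was above background on 1 of 3 treated arrays, Omd fell 10.1-fold, and Phex, an osteoblast peptidase, rose 1.86-fold.

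Inflammation and chemokine genes split at 1 nM. Of the list 11 rose and 7 fell of 28 measured, 11 and 8 adjusted over the list alone, with adjusted p = 0.0496 and 0.192. Besides C3, the chemokine genes Cxcl5, Ccl7 and Cxcl12 rose 7.02-fold, 6.83-fold and 3.54-fold. The median was -0.03 (0.46 under array median scaling), the mean 0.29, and camera ranked the list up. The call was lost under 14 of 18 alternatives (adjusted p = 0.0227 to 0.264), among them without vehicle replicate 3 (0.152), vehicle replicate 1 (0.0842), 1 nM replicate 1 (0.0681) or any 10 nM array (0.0528 to 0.0606), and with the slide as a block (0.0530). Interferon-stimulated genes were lower on balance (1 rose and 11 fell of 27 measured, 1 and 11 adjusted over the list alone, adjusted p = 0.00155 and 0.231). Oasl2, an antiviral gene above background on 2 of 3 vehicle arrays, fell 8.26-fold, the immunoproteasome subunit Psmb8 3.33-fold and Isg15 1.98-fold. The median of -0.59 was -0.67, -0.40 and -1.12 with the slide as a block and within slides 1 and 2, with vehicle replicate 3 the vehicle array of slide 2. Macrophage, endothelial and neural markers, fixed as signs of other cell types, were mostly not called (1 rose and 1 fell of 17 measured, 1 and 1 adjusted over the list alone, adjusted p = 0.0830, median -0.30 and 0.12 under array median scaling). The neuronal tubulin gene Tubb3 fell 2.84-fold, and Tek, an endothelial receptor above background on 1 of 3 vehicle arrays, rose 6.61-fold but not in the submitters' table (log2 0.76, adjusted p = 0.290, 4.32e-07 to 0.290 over its alternatives).

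The remaining lists at 1 nM moved less uniformly. In the vitamin D response list 8 rose and 3 fell of 23 measured, 8 and 3 adjusted over the list alone, with adjusted p = 0.0187 and 0.129. Thbd, an anticoagulant receptor known as a vitamin D target, rose 7.07-fold and the calcium pump gene Atp2b1 1.75-fold. The list lost its call within slide 2. Of the muscle atrophy and autophagy list 12 rose and 2 fell of 26 measured, 14 and 2 adjusted over the list alone, with adjusted p = 6.33e-05 and 0.114. The stress sensor gene Sesn1 rose 2.89-fold and the autophagosome gene Map1lc3b 2.01-fold, while Bnip3 and Ddit4, both known to be induced by low oxygen, fell 2.17-fold and 1.81-fold. Heat shock genes were higher on balance (7 rose and 1 fell of 18 measured, 8 and 1 adjusted over the list alone, adjusted p = 0.0101 and 0.129). Hsph1 rose 1.5-fold and Cryab 1.37-fold. That call was lost under 5 of 18 alternatives (adjusted p = 0.00108 to 0.172), within slide 1 among them (0.172). The small heat shock protein gene Hspb8 rose 1.48-fold, a call lost without vehicle replicate 1, 1 nM replicate 2 or 1 nM replicate 3 (adjusted p = 0.0520 to 0.0610). Of the unfolded protein and integrated stress response list 4 rose and 10 fell of 24 measured, 4 and 10 adjusted over the list alone, with adjusted p = 0.0451 and 0.204. Trib3, a stress pseudokinase, fell 2.99-fold and the lipoprotein receptor gene Vldlr rose 3.06-fold. Its median was -0.25 (0.24 under array median scaling), and camera ranked it down although its mean relative to other genes was near 0. The list lost its call under 7 of 18 alternatives (adjusted p = 0.000758 to 0.638), among them with the slide as a block (0.0530) and without vehicle replicate 1 (0.0842), 1 nM replicate 1 (0.0846) or 10 nM replicate 3 (0.0605). Oxidative stress genes (11 rose and 5 fell of 26 measured, 13 and 5 adjusted over the list alone, adjusted p = 0.125) and circadian clock genes (3 rose and 6 fell of 18 measured, 3 and 6 adjusted over the list alone, adjusted p = 0.0839) were not called as lists. Hmox1 rose 1.65-fold and Nqo1 fell 1.96-fold, and in the clock list, whose median was -0.34 and 0.15 under array median scaling, Hlf, above background on 2 of 3 vehicle arrays, rose 2.32-fold and Arntl fell 1.5-fold.

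Several of the lists lie near background, where vehicle replicate 3 read higher. Without that array the medians at 1 nM of the inflammation, interferon, macrophage, osteoblast, circadian and adipocyte lists were 0.01, -0.49, -0.37, -0.16, -0.19 and 0.36. Relative to the mean of the other genes, the shifts of the lists whose median turned under array median scaling were -0.19 for myoblast markers, -0.26 for glycolysis, 0.06 for lipogenesis, 0.00 for the unfolded protein response, -0.17 for Notch and TGF-beta response, -0.17 for the clock, -0.43 for osteoblast markers, 0.47 for inflammation, 0.85 for adipocyte markers and -0.10 for macrophage, endothelial and neural markers. Under array median scaling the numbers of members that rose became 6 for vitamin D response, 12 for sarcomere, 4 for calcium handling, 1 for oxidative phosphorylation, 5 for fatty acid oxidation, 5 for insulin signalling, 5 for atrophy, 1 for unfolded protein, 3 for oxidative stress and 1 for macrophage, and limma called no member of these lists lower. Those that rose and fell became 4 and 1 for myogenic regulators, 0 and 2 for cholesterol synthesis (median -0.57), 2 and 3 for glycolysis, 5 and 11 for matrix (median -0.07), 0 and 4 for interferon (median -0.23), 0 and 3 for fibroblast (median -0.23), 2 and 2 for myoblast, 5 and 1 for lipogenesis, 9 and 3 for inflammation, 3 and 3 for Notch, 1 and 1 for circadian and 2 and 2 for osteoblast. For heat shock limma called 0, with 7 at an unadjusted p under 0.05. Lists not called at 1 nM were called under some alternatives, oxidative stress higher without the filter (0.0481) and within slide 2 (0.00819), macrophage lower with the replicate block (0.0401) and within slide 2 (0.0153), Notch lower with normexp (0.0357), quantile (0.0294) and within slide 1 (0.00504) and adipocyte higher with normexp, quantile and submitters' values (0.0203 to 0.0441) and within slide 1 (0.000444), in ranges of 0.00819 to 0.792, 0.0153 to 0.471, 0.00504 to 0.970 and 0.000444 to 0.970 over their alternatives. Genes named here that gained a call without vehicle replicate 3, with log2 difference, adjusted p and range over the alternatives, included Adipoq (5.99, 4.59e-06, 1.06e-07 to 0.204), Ppp1r14d (1.07, 0.0166, 0.00592 to 0.860) and Timp3 (-0.24, 0.0437, 0.00875 to 0.592). Array median scaling ended the calls of Arntl, Bnip3, Cox8b, Cryab, Cyp51, Ddit4, Fdps, G0s2, Hmox1, Hspb8, Hsph1, Isg15, Jag1, Myom3, Nfatc2, Nqo1, S100a4, Slc2a1, Tagln, Trib3 and Tubb3 (adjusted p = 0.0514 to 0.873), and the slide 1 fit those of Arntl, Atp2a2, Atp2b1, Cebpb, Cox7a1, Cox8b, Cryab, Hlf, Hmox1, Hspb8, Hsph1, Insr, Myom3, Nqo1 and Plin4 (0.0544 to 0.516). The quantile, normexp or submitters' values ended those of Cenpf, Hlf, Nqo1, Phex, Psmb8 and Tek (0.0537 to 0.488), and the mean of a gene's probes those of Hmox1, Isg15 and Nfatc2 (0.0601 to 0.871).

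**Figure D2:**
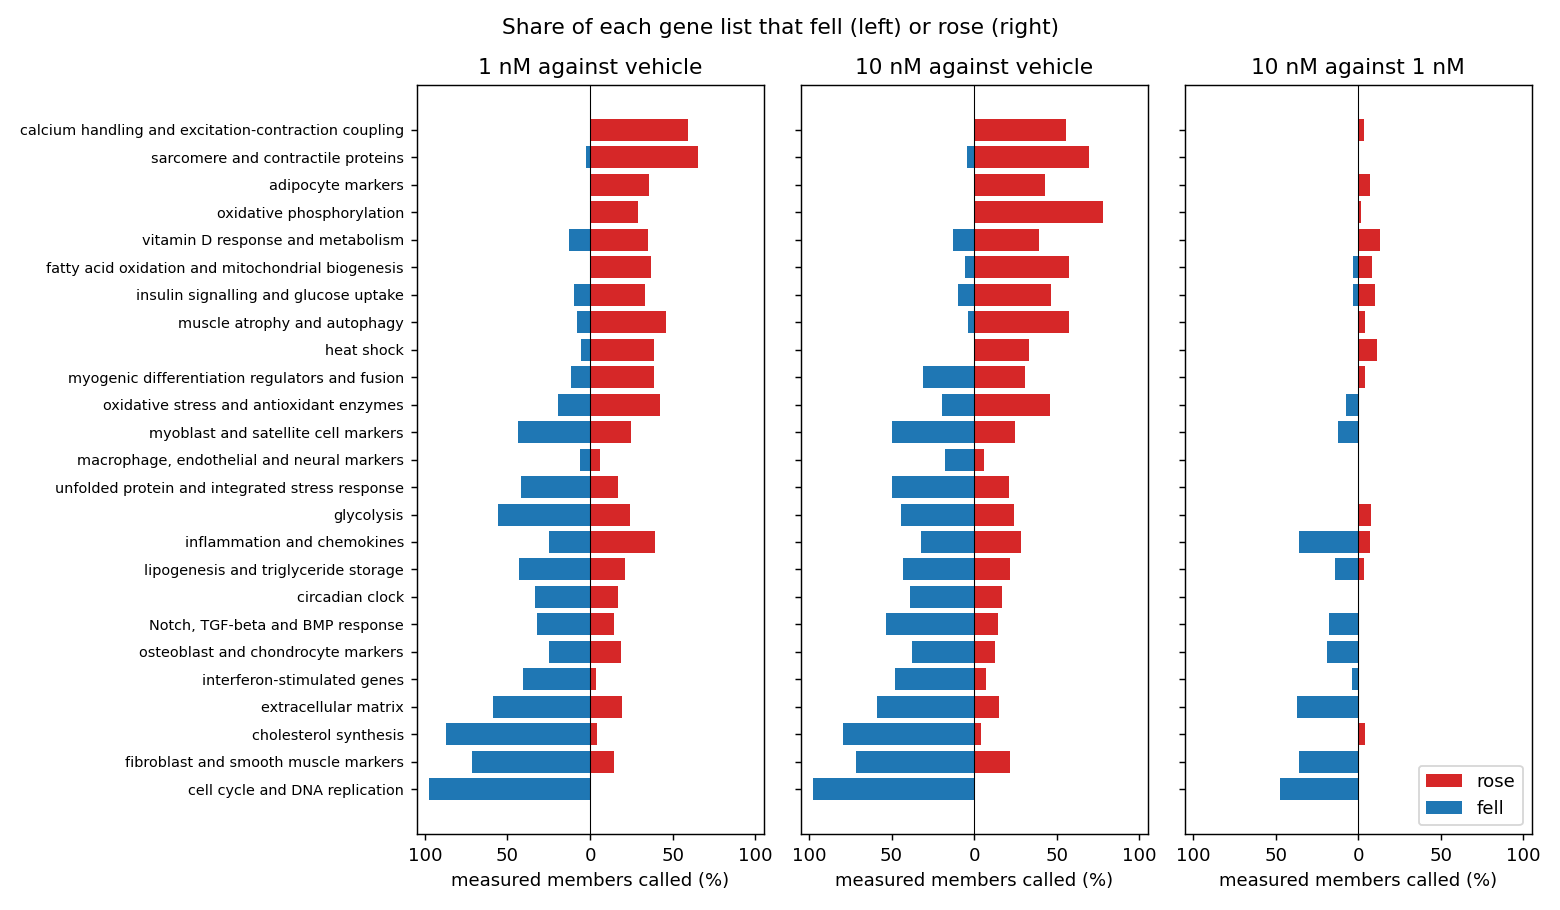
Share of the measured members of each of 25 fixed gene lists that was called higher (bars to the right) or lower (bars to the left) in each comparison, in percent of members measured. Of 40 cell cycle genes 39 fell at each dose against vehicle. Of 69 oxidative phosphorylation genes 20 rose at 1 nM and 54 at 10 nM. Under array median scaling 1 and 9 rose, or 5 and 44 when vehicle replicate 3 was also left out.

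The comparison of 10 nM with vehicle (n = 3 per group) addresses the higher dose. C3 rose 161-fold (log2 7.33, SE 0.14, adjusted p = 6.19e-08), Rarres2 166-fold, and Hp, the haemoglobin-binding acute-phase protein, above background on 2 of 3 vehicle arrays, 80.9-fold. The other C3 probe stood at log2 3.55 and another Ankrd55 probe at 3.11. S100g rose at least 66.5-fold, Grpr at least 77.8-fold, Sprr2h at least 64.3-fold and Ankrd55 at least 20.5-fold. The lowest genes again included Car9, Cilp and mitotic genes, with Car9 118-fold (SE 0.24 on the log2 scale), Car12 at least 64.3-fold, Cilp 106-fold, Aspn at least 27.5-fold, Depdc1a at least 33.1-fold, Kif2c at least 28.4-fold, Kif15 at least 16.3-fold, Ska1 62.2-fold and Kif18b 54.3-fold lower. Ptn, the heparin-binding growth factor pleiotrophin, fell 64.9-fold, the oxidised lipoprotein receptor gene Olr1 at least 13.6-fold and Clec1a, a lectin receptor, at least 11.4-fold (adjusted p = 0.00833). On 10 nM arrays Ska1 was above background on 2 of 3 and Kif18b on 1 of 3.

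Mmp13, Adipoq, the adipocyte hormone adiponectin, Fabp4, Mmp3 and Wfdc17, each above background on 1 of 3 vehicle arrays, rose by 9.53, 7.67, 7.59, 7.49 and 6.66 on the log2 scale (adjusted p = 0.000482, 0.00474, 0.00151, 0.000912 and 0.00173). Without vehicle replicate 3 these were 11.04, 9.58, 9.10, 8.82 and 7.99, as bounds at least 439-fold, 216-fold, 175-fold, 116-fold and 61.6-fold. Without vehicle replicate 1 they were 8.57, 6.52, 6.87, 6.62 and 5.79, and without vehicle replicate 2 Adipoq was 6.92 and Fabp4 6.79. The fitted value of Grpr was 7.99, with 7.09 and 8.90 without vehicle replicates 1 and 2. By limma 6616 of 21926 genes (30.2%) were called at 10 nM, 3393 higher and 3223 lower, of which 701 and 1340 by at least 2-fold. The groups did not overlap in 9607 genes (43.8%, against 10% by chance). The count was 5604 with the slide as a block, 2574 within slide 1, 9990 within slide 2 and 7137 without vehicle replicate 3, and array median scaling called 2529 genes with 67.1% higher, against 51.3% in the main setting. Within slide 1 108 of 120 named genes kept their call.

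Proliferation genes fell at 10 nM as they had at 1 nM. In the cell cycle list 0 rose and 39 fell of 40 measured, 0 and 39 adjusted over the list alone, with adjusted p = 5.26e-31 and 0.0253. Mki67 fell 44.4-fold (SE 0.09 on the log2 scale), Birc5 32.4-fold and Ccna2 26.1-fold. The median was -4.24, or -4.12 with members below background at their bound, and -4.17, -4.17 and -4.24 with the slide as a block and within slides 1 and 2. Myoblast markers again split (4 rose and 8 fell of 16 measured, 4 and 8 adjusted over the list alone, adjusted p = 0.25, median -0.19 and 0.25 under array median scaling). Cd34 fell 15.8-fold and Id2 3.19-fold, and Id3 rose 4.59-fold. Sarcomere genes were higher (32 rose and 2 fell of 46 measured, 37 and 2 adjusted over the list alone, adjusted p = 7.70e-12 and 0.0920). Myh2 rose 4.59-fold, Myh7 2.68-fold and Myl2 2.99-fold. The median of 0.48 was 0.49, 0.46 and 0.53 in the slide settings. So were calcium handling genes (15 rose and 0 fell of 27 measured, 19 and 1 adjusted over the list alone, adjusted p = 2.77e-07 and 0.0920). Cacna2d1 rose 3.57-fold and Atp2a2 2.30-fold. The median of 0.52 was 0.50, 0.56 and 0.51 in the slide settings. Myogenic regulators were not called (8 rose and 8 fell of 26 measured, 8 and 8 adjusted over the list alone, adjusted p = 0.160). Igfbp5 rose 4.28-fold and Cdkn1c fell 6.63-fold.

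More oxidative phosphorylation genes rose at 10 nM. In that list 54 rose and 0 fell of 69 measured, 63 and 0 adjusted over the list alone, with adjusted p = 1.40e-17 and 0.0691. Cox7a1 rose 4.50-fold and Cox8b 1.92-fold. The median of 0.41 was 0.42, 0.42 and 0.42 with the slide as a block and within slides 1 and 2. In the fatty acid oxidation list 20 rose and 2 fell of 35 measured, 23 and 3 adjusted over the list alone, with adjusted p = 4.79e-07 and 0.0551. Fabp3 rose 2.74-fold and Etfa 2.05-fold. Insulin signalling genes were higher (14 rose and 3 fell of 30 measured, 15 and 3 adjusted over the list alone, adjusted p = 0.000201 and 0.133), among them Tbc1d4, a regulator of glucose transporter traffic (4.92-fold, with another probe at log2 1.13), and Irs2 (2.78-fold). Glycolysis genes were not called as a list (6 rose and 11 fell of 25 measured, 8 and 14 adjusted over the list alone, adjusted p = 0.160, median -0.24 and 0.29 under array median scaling). Slc16a3 fell 6.31-fold and Ldhb rose 4.38-fold. Cholesterol synthesis genes were lower (1 rose and 19 fell of 24 measured, 1 and 19 adjusted over the list alone, adjusted p = 1.49e-07 and 0.0952). Stard4 fell 3.45-fold. The median of -0.90 was -0.95, -0.88 and -0.97 in the slide settings. Lipogenesis genes were not called as a list (6 rose and 12 fell of 28 measured, 10 and 13 adjusted over the list alone, adjusted p = 0.403, median -0.27 and 0.26 under array median scaling). Dgat1 rose 11.47-fold and G0s2 fell 6.52-fold.

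Adipocyte markers rose in part at 10 nM (6 rose and 0 fell of 14 measured, 6 and 0 adjusted over the list alone, adjusted p = 0.0301 and 0.453). Cebpa rose 5.94-fold, Cebpb 2.11-fold and Fabp5 1.98-fold. This group moves with the array of vehicle replicate 3. Its median of 0.45 was 0.04, 0.71 and -0.56 with the slide as a block and within slides 1 and 2. That call was lost under 5 of 18 alternatives (adjusted p = 0.000174 to 0.655), among them the slide block (0.0536), vehicle replicate 1 left out (0.0551) and vehicle replicate 2 left out (0.0659). Extracellular matrix genes were lower (7 rose and 27 fell of 46 measured, 7 and 28 adjusted over the list alone, adjusted p = 4.75e-07 and 0.0458). Col18a1 fell 35.4-fold, Col6a1 13.2-fold and Thbs2, an inhibitor of blood vessel growth, 8.95-fold. The median of -0.75 was -0.76, -0.87 and -0.77 in the slide settings. Fibroblast and smooth muscle markers were lower (3 rose and 10 fell of 14 measured, 3 and 10 adjusted over the list alone, adjusted p = 4.59e-05 and 0.0458). Cnn1 fell 11.8-fold and Pi16 6.24-fold. The median of -1.39 was -1.40, -1.37 and -1.46. Of the Notch, TGF-beta and BMP response list 4 rose and 15 fell of 28 measured, 5 and 16 adjusted over the list alone, with adjusted p = 0.0184 and 0.133 and a median of -0.38 (0.15 under array median scaling). Inhba fell 8.20-fold and Jag1 3.77-fold. The list lost its call under 3 of 18 alternatives (adjusted p = 0.000845 to 0.586), vehicle replicate 2 left out (0.0554) and slide 2 alone (0.586) among them. Osteoblast and chondrocyte markers were lower on balance (2 rose and 6 fell of 16 measured, 2 and 8 adjusted over the list alone, adjusted p = 0.0252 and 0.162). Dmp1 fell at least 22.4-fold and Runx2, a bone transcription factor, 3.16-fold. That call was lost under 6 of 18 alternatives (adjusted p = 0.00486 to 0.378), among them vehicle replicate 2 left out (0.0659) and normexp (0.244).

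Inflammation genes were not called as a list at 10 nM (8 rose and 9 fell of 28 measured, 9 and 10 adjusted over the list alone, adjusted p = 0.356), with a median of -0.25 (0.27 under array median scaling) while camera ranked the list up, and down without vehicle replicate 3. Cxcl12 rose 4.49-fold, the cytokine gene Il6 fell 13.6-fold and Tnfaip3, a brake on NF-kappaB, 2.75-fold. Interferon-stimulated genes were lower on balance (2 rose and 13 fell of 27 measured, 3 and 15 adjusted over the list alone, adjusted p = 0.00418 and 0.288). Oasl2 fell 13.8-fold and Psmb8 4.79-fold. The median of -0.72 was -0.73, -0.48 and -1.03 in the slide settings. Oasl2 and Psmb8 were above background on 2 of 3 arrays at 10 nM. Macrophage, endothelial and neural markers were mostly not called (1 rose and 3 fell of 17 measured, 1 and 2 adjusted over the list alone, adjusted p = 0.160, median -0.19 and 0.20 under array median scaling). Tubb3 fell 3.78-fold, and Tek, above background on 1 of 3 vehicle arrays, rose 6.86-fold but not in the submitters' table (log2 0.81, adjusted p = 0.242, 9.94e-07 to 0.242 over its alternatives). Vwf and Mbp fell 1.97-fold and 2.47-fold (adjusted p = 0.0242 and 0.0425), calls lost under 9 and 13 of 27 alternatives (0.00905 to 0.722 and 0.00455 to 0.143). Among these were the fits without 10 nM replicates 1 and 3 for Vwf (0.0639 and 0.0836) and without any 1 nM or 10 nM array for Mbp (0.0534 to 0.122).

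In the vitamin D response list 9 rose and 3 fell of 23 measured, 10 and 3 adjusted over the list alone, at 10 nM, with adjusted p = 0.00383 and 0.0920. Thbd rose 19.2-fold. The list lost its call within slide 2. Muscle atrophy and autophagy genes were higher on balance (15 rose and 1 fell of 26 measured, 16 and 1 adjusted over the list alone, adjusted p = 4.41e-06 and 0.0920). Klf15, a glucocorticoid-responsive factor, rose at least 4.55-fold, Sesn1 3.58-fold and the ubiquitin ligase gene Trim63 2.87-fold. Heat shock genes were higher on balance (6 rose and 0 fell of 18 measured, 9 and 0 adjusted over the list alone, adjusted p = 0.00418 and 0.0920). Hspb7, a muscle chaperone gene, rose 2.69-fold and Hsph1 1.81-fold. That call was lost under 5 of 18 alternatives (adjusted p = 0.000324 to 0.163), within slide 1 among them (0.163). Circadian clock genes were lower on balance (3 rose and 7 fell of 18 measured, 3 and 8 adjusted over the list alone, adjusted p = 0.0497 and 0.231, median -0.36 and 0.17 under array median scaling). Bhlhe40, a clock repressor, fell 1.91-fold and Hlf, above background on 2 of 3 vehicle arrays, rose 3.93-fold. The circadian call was lost under 10 of 18 alternatives (adjusted p = 0.0128 to 0.328), among them without vehicle replicate 2 (0.0739), 10 nM replicate 1 (0.105), 10 nM replicate 2 (0.0516) or 1 nM replicate 1 (0.0567). The oxidative stress list (12 rose and 5 fell of 26 measured, 12 and 5 adjusted over the list alone, adjusted p = 0.227) and the unfolded protein list (5 rose and 12 fell of 24 measured, 6 and 12 adjusted over the list alone, adjusted p = 0.265, median -0.23 and 0.29 under array median scaling) were not called. The metal-binding gene Mt1 rose 2.02-fold, Nqo1 fell 2.24-fold, Txnip, an inhibitor of thioredoxin, 2.53-fold and Trib3 2.6-fold, and Vldlr rose 3.89-fold.

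Without vehicle replicate 3 the medians at 10 nM of the inflammation, interferon, macrophage, osteoblast, circadian and adipocyte lists were -0.17, -0.64, -0.20, -0.53, -0.28 and 0.76. Relative to the mean of the other genes, the shifts at 10 nM were -0.29 for myoblast markers, -0.13 for glycolysis, 0.03 for lipogenesis, 0.09 for the unfolded protein response, -0.38 for Notch and TGF-beta response, -0.22 for the clock, 0.14 for inflammation and -0.08 for macrophage, endothelial and neural markers. Under array median scaling the numbers of members that rose became 17 for sarcomere, 9 for oxidative phosphorylation, 13 for fatty acid oxidation, 10 for insulin signalling, 9 for atrophy, 3 for heat shock, 3 for unfolded protein and 6 for oxidative stress, and limma called no member of these lists lower. Those that rose and fell became 8 and 1 for vitamin D response, 4 and 2 for myogenic regulators, 0 and 5 for cholesterol synthesis (median -0.37), 3 and 3 for glycolysis, 5 and 15 for matrix (median -0.22), 0 and 4 for interferon (median -0.29), 1 and 6 for fibroblast (median -0.86), 4 and 2 for myoblast, 7 and 3 for lipogenesis, 6 and 3 for inflammation, 3 and 5 for Notch, 1 and 1 for circadian, 1 and 2 for osteoblast and 2 and 1 for macrophage. Lists not called at 10 nM were called under some alternatives, glycolysis lower with normexp, quantile and submitters' values (0.00486 to 0.00729) and within slide 1 (0.00776), unfolded protein lower with the first 3 of these (0.0125 to 0.0171), myoblast lower with quantile (0.0414) and within slide 1 (0.0489), myogenic regulators higher (0.00591), oxidative stress higher (0.0174) and macrophage lower (0.0210) within slide 2, in ranges of 0.00486 to 0.774, 0.0125 to 0.944, 0.0414 to 0.888, 0.00591 to 0.995, 0.0174 to 0.859 and 0.0210 to 0.859 over their alternatives. Array median scaling ended the calls of Bhlhe40, Id2, Mbp, Nqo1, Runx2, Tnfaip3, Trib3, Txnip and Vwf (adjusted p = 0.0532 to 0.411), the slide 1 fit those of Fabp5, Hsph1 and Mbp (0.0600 to 0.143), and the quantile, normexp or submitters' values those of Nqo1, Psmb8, Runx2, Tek and Vwf (0.0589 to 0.722). The Clec1a call was lost within slide 2. Without vehicle replicate 3 array median scaling turned no list median at 10 nM (glycolysis -0.16). It then called 28 higher and 0 lower for sarcomere and 44 and 0 for oxidative phosphorylation. For cholesterol synthesis it called 0 and 15, for matrix 8 and 25 and for fibroblast 3 and 9.

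The comparison of 10 nM with 1 nM (n = 3 per group) tests the difference between the doses itself. Among genes with a symbol that passed the test and whose arrays did not overlap, the highest besides Cyp24a1 were Cyp26b1, which degrades retinoic acid (5.97-fold, SE 0.10 on the log2 scale, adjusted p = 0.000150), Ppp1r14d (11.0-fold, above background on 1 of 3 arrays at 1 nM, adjusted p = 0.00649), Nppc, which encodes C-type natriuretic peptide (at least 3.19-fold, adjusted p = 0.0369), and Klhl29 (at least 2.19-fold, adjusted p = 0.00283). Lowest among such genes were Postn, which encodes the matrix protein periostin, 5.90-fold (SE 0.14 on the log2 scale, adjusted p = 0.000230), Ptn 5.44-fold, the Wnt modulator gene Sfrp2 4.53-fold, Lrrc17 4.12-fold and Cilp 3.95-fold lower at 10 nM. Vehicle replicate 3 enters this comparison only in the shared spread. Without it named genes gained calls at the same log2 difference (given with adjusted p and range over alternatives). They included Adipoq (3.59, 0.000337, 7.00e-07 to 0.681), Fabp4 (0.65, 0.00781, 0.00210 to 1.000) and Igf1 (-0.53, 0.0207, 0.00297 to 1.000). Others were Mmp13 (1.26, 0.0148, 9.84e-05 to 1.000), Rarres2 (0.62, 0.00698, 0.00206 to 1.000) and Sprr2h (1.16, 0.00473, 0.00175 to 0.615). The Nppc call was lost with the replicate (0.129) or slide block (0.122) and without vehicle replicate 1, 1 nM replicate 1 or 3 or any 10 nM array (0.0684 to 0.154, 0.00184 to 0.315 over its alternatives). Ppp1r14d was lost with the slide as a block (0.0556, 2.67e-05 to 0.0927), and Klhl29 in the submitters' table (log2 0.79, 0.942, 0.000497 to 0.942).

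By limma 840 of 21926 genes (3.83%) were called between the doses, 350 higher and 490 lower at 10 nM, 74 and 90 of them by at least 2-fold. The groups did not overlap in 5272 genes (24.0%, against 10% by chance). With the replicate number as a block 460 genes were called, 450 of them among the 840. The 2 groups alone gave 667 with it. With the slide as a block 354 genes were called, a fall that can also reflect 10 nM replicate 3, alone on slide 3. Within slide 1, which holds 1 array of each dose, 5 genes were called, none of the 840, and 1516 had an unadjusted p under 0.05. Within slide 2, with 2 arrays at 1 nM and 1 at 10 nM, limma called 0 genes and 3374 had an unadjusted p under 0.05. The count was 1268 without vehicle replicate 3, and 365, 387 and 435 without 1 nM replicates 3, 2 and 1 and 466, 435 and 421 without 10 nM replicates 1, 2 and 3. Array median scaling called 58 genes, 69.0% of them higher, against 41.7% in the main setting. Of 60 named genes called between the doses 36 kept the call with the slide and 47 with the replicate number as a block. Within slide 1 or 2, where limma called at most 5 genes, 0 kept it, and 21 lost it with an array left out.

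Matrix, fibroblast and inflammation genes were lower at 10 nM than at 1 nM. In the extracellular matrix list 0 rose and 17 fell of 46 measured, 1 and 21 adjusted over the list alone, with adjusted p = 6.04e-11 and 0.0216. Col18a1 fell 3.24-fold and the protease inhibitor gene Timp3 2.01-fold, and the median of -0.30, or -0.24 with members below background at their bound, was -0.24, -0.29 and -0.24 with the slide as a block and within slides 1 and 2. Fibroblast and smooth muscle markers were lower (0 rose and 5 fell of 14 measured, 1 and 7 adjusted over the list alone, adjusted p = 3.00e-06 and 0.0216). Pi16 fell 2.27-fold and Ly6a 2.10-fold. The median of -0.37 was -0.35, -0.12 and -0.42. In the inflammation list 2 rose and 10 fell of 28 measured, 5 and 10 adjusted over the list alone, with adjusted p = 0.00157 and 0.0767. Cxcl1, Il6, Cxcl5 and Ccl2 fell 3.23-fold, 3.02-fold, 2.94-fold and 2.88-fold. Cell cycle genes were lower still (0 rose and 19 fell of 40 measured, 0 and 26 adjusted over the list alone, adjusted p = 3.83e-23 and 0.0216). Mki67 fell 1.99-fold and Bub1b 2.02-fold. The median of -0.54 was -0.50, -0.49 and -0.49 in the slide settings. Of the Notch, TGF-beta and BMP response list 0 rose and 5 fell of 28 measured, 1 and 6 adjusted over the list alone, with adjusted p = 0.000111 and 0.0533. Inhba fell 1.91-fold. Of osteoblast and chondrocyte markers 0 rose and 3 fell of 16 measured, 1 and 5 adjusted over the list alone, with adjusted p = 0.00119 and 0.0832. Phex fell 2.80-fold. Myogenic regulators were lower as a list (1 rose and 0 fell of 26 measured, 1 and 5 adjusted over the list alone, adjusted p = 0.00770 and 0.244), although the member that passed, Igfbp5, rose 1.40-fold. That call of the list was lost under 2 of 18 alternatives (adjusted p = 0.000257 to 0.244), the fit without 10 nM replicate 1 among them (0.0678). The osteoblast call was lost with quantile normalization (0.0837, 0.000534 to 0.0837 over its alternatives), and the Igfbp5 call without 1 nM replicate 1 or 2 or any 10 nM array (0.0811 to 0.0984) and with the replicate number as a block (0.0515, 0.00513 to 1.000 over its alternatives).

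Oxidative phosphorylation genes were higher at 10 nM than at 1 nM as a list (1 rose and 0 fell of 69 measured, 1 and 0 adjusted over the list alone, adjusted p = 9.07e-21 and 0.0533). The median of 0.20 was 0.22, 0.27 and 0.18 in the slide settings. Cox7a1 rose 2.38-fold (adjusted p = 0.00586), and its call was lost with the slide as a block (0.0516, 0.000644 to 0.465 over its alternatives). Further lists were higher. In the vitamin D response list 3 rose and 0 fell of 23 measured, 4 and 1 adjusted over the list alone, with adjusted p = 0.00130 and 0.0767. Thbd rose 2.71-fold. For fatty acid oxidation 3 rose and 1 fell of 35 measured, 7 and 2 adjusted over the list alone, with adjusted p = 0.000735 and 0.101. In muscle atrophy and autophagy 1 rose and 0 fell of 26 measured, 4 and 0 adjusted over the list alone, with adjusted p = 0.000607 and 0.136. Ddit4 rose 1.81-fold. For glycolysis 2 rose and 0 fell of 25 measured, 3 and 1 adjusted over the list alone, with adjusted p = 0.00130 and 0.244. Pfkfb3 rose 1.80-fold. In cholesterol synthesis 1 rose and 0 fell of 24 measured, 2 and 0 adjusted over the list alone, with adjusted p = 0.00112 and 0.244. Hsd17b7 rose 1.46-fold. For insulin signalling 3 rose and 1 fell of 30 measured, 6 and 1 adjusted over the list alone, with adjusted p = 0.00710 and 0.244. Tbc1d4 rose 2.78-fold. Of adipocyte markers 1 rose and 0 fell of 14 measured, 2 and 0 adjusted over the list alone, with adjusted p = 0.00710 and 0.347. For heat shock 2 rose and 0 fell of 18 measured, 4 and 0 adjusted over the list alone, with adjusted p = 0.0408 and 0.231. Calls were lost within slide 1 for fatty acid oxidation (0.0866), atrophy (0.0866), glycolysis (0.0986), cholesterol (0.101) and insulin signalling (0.247), and within slide 2 for cholesterol (0.323) and glycolysis (0.0717), in ranges of 0.000102 to 0.101, 3.98e-05 to 0.136, 0.000196 to 0.244, 0.000219 to 0.323 and 0.000513 to 0.247 over their alternatives. The insulin call was also lost with the slide as a block (0.0503) and without 1 nM replicate 1 (0.0547) or 10 nM replicate 3 (0.0515). Heat shock lost its call under 13 of 18 alternatives (adjusted p = 0.0119 to 0.463), among them the replicate block (0.0720) and the fits without vehicle replicate 3 (0.0618), vehicle replicate 2 (0.0800), 1 nM replicate 1 (0.171), 10 nM replicate 2 (0.0953) or 10 nM replicate 3 (0.103).

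The other lists were not called between the doses. Of sarcomere genes 0 rose and 0 fell of 46 measured, 0 and 0 adjusted over the list alone, with adjusted p = 0.113 and 9 genes at an unadjusted p under 0.05 by limma. Myh2 was at a log2 difference of 0.31 (adjusted p = 0.104). Of calcium handling genes 1 rose and 0 fell of 27 measured, 1 and 0 adjusted over the list alone, with adjusted p = 0.658. Of myoblast markers 0 rose and 2 fell of 16 measured, 1 and 2 adjusted over the list alone, with adjusted p = 0.140, and Id2 fell 1.80-fold. Of lipogenesis genes 1 rose and 4 fell of 28 measured, 4 and 5 adjusted over the list alone, with adjusted p = 0.902. Abcg1 fell 2.91-fold and Dgat1 rose 1.65-fold. Of interferon-stimulated genes 0 rose and 1 fell of 27 measured, 0 and 1 adjusted over the list alone, with adjusted p = 0.513, and of oxidative stress genes 0 rose and 2 fell of 26 measured, 0 and 2 adjusted over the list alone, with adjusted p = 0.902. Of unfolded protein response genes 0 rose and 0 fell of 24 measured, 0 and 0 adjusted over the list alone, with adjusted p = 0.137 and 6 at an unadjusted p under 0.05 by limma. Limma called 0 of the circadian genes, 1 and 1 adjusted over the list alone and 3 at an unadjusted p under 0.05, with adjusted p = 0.140 and Hlf at a log2 difference of 0.76 (adjusted p = 0.0561). Hlf was called without vehicle replicate 1, 2 or 3 (0.0208, 0.0158 and 0.0359, 0.0108 to 0.858 over its alternatives). For macrophage, endothelial and neural markers limma also called 0 of 17 (0 and 1 adjusted over the list alone, 1 at an unadjusted p under 0.05, adjusted p = 0.855), with Tubb3 at -0.42 (adjusted p = 0.0575). Tubb3 was called without vehicle replicate 2 or 3 (0.0378 and 0.0467, 0.00843 to 1.000 over its alternatives). With the slide as a block the myoblast (0.0365) and circadian lists (0.0479) were called, as were the myoblast list with the quantile, normexp and submitters' values (0.0349 to 0.0416), the circadian list within slide 2 (0.0344), the sarcomere list without 1 nM replicate 3 (0.0178) and the unfolded protein list without 10 nM replicate 1 (0.0459). Their ranges over the alternatives were 0.0349 to 0.290, 0.0344 to 0.482, 0.0178 to 0.839 and 0.0459 to 0.874.

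Array median scaling ended the calls between the doses of Abcg1, Bub1b, Ccl2, Cilp, Col18a1, Cox7a1, Cxcl5, Ddit4, Dgat1, Hsd17b7, Id2, Igfbp5, Il6, Inhba, Ly6a, Mki67, Pfkfb3, Phex, Pi16, Tbc1d4, Thbd and Timp3 (adjusted p = 0.0652 to 1.000). Under that scaling 2 matrix genes and 1 inflammation gene fell and 1 gene of the vitamin D list rose. In every other list limma called 0 genes, with 0 to 6 of a list at an unadjusted p under 0.05. The quantile, normexp or submitters' values ended the calls of Bub1b, Cxcl1, Cxcl5, Phex and Thbd (0.0697 to 0.870), the slide block also that of Dgat1 (0.0516), and the mean of a gene's probes those of Hsd17b7 (0.486) and Tbc1d4 (0.209).

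Set side by side, the responses to the 2 doses lay close together. Of the genes called at 1 nM, 4708 (90.8%) were also called at 10 nM, 2304 higher in both, 2390 lower in both and 14 in opposite directions, against 400.3 and 382.0 for independent lists of those sizes. Another 478 genes were called at 1 nM alone and 1908 at 10 nM alone, which is no test of a difference between the doses. Across genes, which are not independent replicates, the 2 sets of log2 changes had a Pearson r of 0.943 and a covariance of 0.616. In 100 simulations of unchanged groups with shared controls of equal spread these were 0.50 and 0.0460, a difference in covariance of 0.570. The real controls, among them an array that stood apart, were not modelled and are too few to split. Part of the excess over independent lists can come from them. Of 4708 genes called at both doses 3562 changed in the same direction and more at 10 nM, with a slope of 1.16 of the 10 nM on the 1 nM change. The changes had the same sign in 89.5% of genes, against 66.7% in the simulations.

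**Figure D3:**
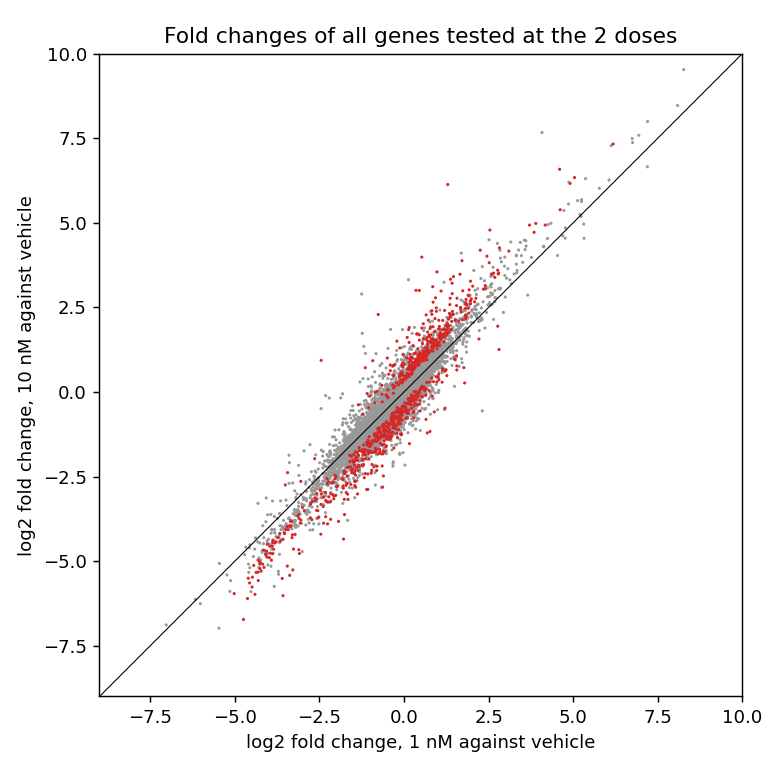
Log2 fold change against vehicle at 1 nM (x axis) and at 10 nM (y axis) for 21926 genes, with the diagonal marking equal change and the 840 genes called between the doses in red. Most points lie along the diagonal (r = 0.943 across genes).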

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

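The tests of an even haze, of the vehicle replicate 3 array on cell cycle genes, of undifferentiated myoblasts, of full adipocytes and of the splits by pairs were chosen only after the result was seen. The marks for non-uniform spots served only to leave out spots, and the negative control spots entered no comparison. Both set the array of vehicle replicate 3 apart from the other vehicle arrays, with 6124 non-uniform spots and a raw median of 44 intensity units on its negative control spots.

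Dim probes read higher on that array. An even haze is argued against, since the negative control spots exceeded the other arrays by 14.5 units and 4949 dim gene probes by 109, a ratio of 0.133. Non-specific binding of labelled RNA, stronger at higher GC content, is a candidate explanation, as the excess correlated with probe GC content (r = 0.1885, rho = 0.309 across probes) and had a median of 69.1 units among probes of the lowest and 171 among those of the highest GC content. For RNA of macrophage, endothelial or neural cells, the median log2 excess of 18 marker probes, 0.823 against 0.424 for random lists of like level, lay at percentile 93.7 of 10000 lists, short of the bound set beforehand. That value lies within the spread of random lists, and this explanation was kept open only after it was seen. On vehicle replicates 1 and 2, 15 of the probes were above background.

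Cell cycle genes were lower at both doses. The tables argue against the vehicle replicate 3 array as the cause, since the median at 10 nM was -4.195 without it, and against a difference between slides, since it was -4.175 within slide 1. A loss of undifferentiated myoblasts as a whole stays open, as 6 of 7 markers that do not follow the cell cycle fell with a median of -1.105 but moved apart, with Cd34 falling nearly as much as cell cycle genes. That median met the bound first set against this explanation, and the bound was loosened after the values were seen, because a marker that myotubes also express falls less when myoblasts are lost. Calcitriol, the difference the design names, stays among the open explanations.

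Adipocyte genes were higher at 10 nM. The array of vehicle replicate 3 as the cause is argued against, since 6 of 6 called members stayed called without it. For Adipoq, Fabp4 and Plin4, which were dim in vehicle and read highest on that array, leaving it out had to raise the fold and decides nothing. Cebpa, which read lowest on it, Cebpb and Fabp5 rose by 2.42, 1.07 and 1.01 on the log2 scale without it. A share of cells turned into full adipocytes stays open, because 5 of 12 transcripts restricted to adipocytes rose, between the bounds set for it.

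Other splits of the 6 arrays in each comparison were counted. For 5186, 6616 and 840 genes, 1 of 10 splits, the real one, gave as many, and limma called at most 0 in the others, where up to 2173, 2020 and 1402 genes had an unadjusted p under 0.05. The 10 splits are too few for a share under 0.05. With replicate numbers taken as pairs of the 2 doses, the real split parts 3 pairs. So do 3 of the other splits, in which at most 134 genes had an unadjusted p under 0.05. The other 6 part 1 pair, and the 1402 came from one of these. With the number as a block limma called 460 genes in the real split and 0 in the others, where up to 1095 had an unadjusted p under 0.05.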

How the results depend on the processing

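The 2-group replicate block and the normexp and median scaling fits without vehicle replicate 3 were chosen after seeing the data. For 303 results on single named genes and 75 on lists, 7515 and 1159 values kept direction and call, 627 and 126 lost a call, 31 and 33 gained one and 6 and 32 changed direction. Of the results that answer a comparison, 221 values stayed as they were, 38 moved, 2 lost a call and 1 gained one. The cause was not tested unless named.

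Counts at 1 nM (5186) and 10 nM (6616) became 1512 and 2529 with array median scaling, 11450 and 10407 with array weights, 1594 and 2574 within slide 1 and 10421 and 9990 within slide 2. A log2 change of at least 1 left 1453 and 2041, and an adjusted p under 0.01 left 3091 and 4330, which follows from the stricter thresholds. The count between the doses (840) was 555 with normexp, 556 with quantile normalization, 58 with array median scaling, 367 in the submitters' table, 536 without the filter, 1884 with array weights, 1351 with only the 2 groups, 354 with the slide as a block, 5 within slide 1 and 0 within slide 2 by limma (3374 at an unadjusted p under 0.05), 164 with a log2 change of at least 1 and 370 at an adjusted p under 0.01. Fewer arrays enter the within-slide fits. The weights' estimate, which gave vehicle replicate 3 a weight of 0.128, ended with a warning that its convergence tolerance was not reached. Without vehicle replicate 3, median scaling called 3635, 5441 and 572 genes and normexp 5576, 6973 and 1139.

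Leaving out 1 array gave 3507 to 5568 genes at 1 nM, 5093 to 7137 at 10 nM and 365 to 1268 between the doses. Cyp24a1 ran from 1.14 to 1.57 and 5.97 to 6.40, Vdr from 0.05 to 0.13 and 1.57 to 1.64, the lists called from 15 to 17, 13 to 17 and 14 to 17, and r between the doses from 0.925 to 0.948. Hspb8 and Plin4 lost their call at 1 nM, Vwf and Mbp at 10 nM, and 21 of 60 named genes between the doses. At 1 nM the Cyp24a1 call was lost with quantile normalization (2.42) and within slide 1 (1.16), and Vdr gained one with array weights (0.192). With the estimated correlation 1, 3 and 3 lists were called, and within slide 1 10 lists between the doses.

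Some values changed direction. Dnajb1 at 1 nM was 0.0159 with array median scaling. Ciart was 0.0116 with normexp, 0.278 with quantile normalization and 0.0637 in the submitters' table at 1 nM, and 0.264 and 0.0173 in the latter pair at 10 nM. None of the lists that follow was called in that comparison. The myoblast, lipogenesis and Notch lists were at 0.0632, 0.229 and 0.0893 within slide 2 at 1 nM. At 10 nM the myogenic list was at -0.0385 with quantile normalization and -0.0167 within slide 1, lipogenesis and glycolysis at 0.195 and 0.190 within slide 2, inflammation at -0.0341 within slide 1 and 0.0704 to 0.193 with 1 array left out, the lowest of these without vehicle replicate 3, where camera's direction turned, and the macrophage list at 0.125 within slide 1. Between the doses the calcium list was at -0.0318 with normexp, -0.0311 in the submitters' table, -0.0666 with the slide as a block, -0.0924 within slide 2 and -0.0541 to 0.0661 with 1 array left out. Lipogenesis was at -0.0943 within slide 1 and -0.0692 to 0.0342 with 1 array left out, oxidative stress at -0.000188 with normexp and -0.0416 to 0.0872 with 1 left out, and the macrophage list at 0.0714 with the slide as a block, 0.172 within slide 1 and -0.0476 to 0.0599 with 1 left out.

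With the replicate number as a block (replicate block), 4667 genes were called at 1 nM, 6211 at 10 nM and 460 between the doses. Vehicle arrays did not pair with the others by number (r from -0.421 to 0.055), and 4 of 9 samples correlated best with a sample of their own number. Of lists called, the block ended only inflammation at 1 nM, circadian at 10 nM and heat shock between the doses. It gave the macrophage list a call at 1 nM (0.0401). Of genes the report names between the doses it ended only the calls of Nppc and Igfbp5. Scan dates, divided as the slides, gave no separate alternative. Signal over background limits the dim genes, of which 43 were not above background on any vehicle array.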

Other observations

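The lists of this part and their tests were chosen after values were seen, and the hypoxia and complement tests were fixed before their own results. Besides Car9 and Car12, several genes known to rise in low oxygen were called lower at 10 nM. Ndrg1 fell 5.90-fold, the collagen prolyl hydroxylase genes P4ha2 and P4ha1 2.87-fold and 2.02-fold, Ankrd37 2.64-fold and the oxidoreductase gene Ero1a 2.48-fold. Vegfa, the vascular growth factor, rose 1.79-fold at 1 nM and 2.99-fold at 10 nM, and Selenbp1 rose 2.54-fold at 10 nM. Of 28 hypoxia-responsive genes 17 fell and 3 rose at 1 nM, and 18 fell and 3 rose at 10 nM, a list that includes genes seen beforehand.

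Other secreted and retinoid-handling genes split at 10 nM. Of 12 acute-phase genes 3 rose and 2 fell (camera p = 0.683 with the estimated correlation), with Orm1, above background on 2 of 3 vehicle arrays, 9.95-fold, the lipopolysaccharide-binding protein gene Lbp 4.85-fold and ceruloplasmin (Cp) 3.06-fold higher, and Serpina3g 4.55-fold and Serpina3f, above background on 1 of 3 arrays at 10 nM, 4.58-fold lower. Of 16 retinoid genes 3 rose and 4 fell (camera p = 0.527 with the estimated correlation), with the binding protein gene Crabp2 2.66-fold higher, and Aldh1a3, which makes retinoic acid and was above background on 2 of 3 arrays at 10 nM, 27.4-fold and Adh7, also above background on 2 of 3, 4.82-fold lower.

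The hypothesis on oxygen was that hypoxia-responsive transcripts fell as a set beyond the genes already seen. Of 16 unseen members 8 fell and 2 rose at 10 nM, and camera gave p = 0.08533 with the estimated correlation, direction down. That p missed the threshold set beforehand, which does not show that the set stayed level, so the hypothesis stays open.

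The hypothesis on complement was that its genes rose beyond C3 and Cfb. Of 18 unseen members 5 rose and 5 fell at 10 nM (camera p = 0.8411 with the estimated correlation, direction down), with a median log2 change of -0.26 and quartiles of -0.77 and 0.34. A missed threshold or a direction down had been set beforehand as counting against a rise. With quartiles on both sides of 0 neither decides, a reading made after the values were seen, so this hypothesis stays open too. Serping1 rose 2.15-fold and Masp1 4.04-fold, while Cd59a fell 1.98-fold.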
